A study of Mus musculus and Homo sapiens with 16 samples.

How the data were processed

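DNA methylation was measured by digital restriction enzyme analysis of methylation (DREAM) in 16 libraries of cultured melanocytes. Genomic DNA with added methylation standards is cut first with SmaI, which cuts CCCGGG only where its CpG is unmethylated, and then with XmaI, which cuts the methylated sites left. The 2 enzymes leave different ends, so each sequenced end tells whether its site was methylated. Per the submitters' processing notes, Trim Galore and Bowtie2 were used and the builds were hg19 and mm9; versions and settings are not given in the sources used here.

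The deposited files list 1 library each, with CCCGGG sites of the build, sites without reads included, and their counts of methylated (XmaI end) and unmethylated (SmaI end) reads, per the file headers. The deposited counts are whole numbers, not normalized, and replicates were not pooled. The authors also deposited a raw percent and an adjusted percent of methylation per site. From the values, the raw percent has 0.5 reads added to the methylated and 0.5 to the unmethylated count in all libraries but those of melan-a batch 2, where it is the plain ratio. The adjustment for enzyme efficiency was based on the standards, per the series' design text, and from the values it multiplies the raw odds at every site of a library by 1 factor, from 0.653 to 1.20 in HEMn-DP1 and from 0.405 to 2.06 in melan-a. The rows of the standards took 0.130% to 3.97% of the reads of the HEMn-DP1 libraries and 0.100% to 1.05% of those of melan-a, and were left out of all tests.

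Total reads (M, 1000000 reads) ran from 19.9 to 161 M in HEMn-DP1 and from 2.90 to 14.9 M in melan-a. Sites were tested on the autosomes where every library of the comparison had at least 20 reads, which left 70144 sites in HEMn-DP1 and 19398 in melan-a. At the median depth of the tested sites, 178 to 1031 reads in HEMn-DP1 and 97 to 600 in melan-a, the 95% exact (Clopper-Pearson) interval of a methylation level has a half-width of at most 7.57 and 10.3 percentage points at a level in the middle of the scale. PCR copies are not told apart in these reads, so these intervals cover counting error only.

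UVR was compared with control within each cell type. Methylated and unmethylated reads of each site were fitted with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, 1 effect per library, 1 common negative binomial dispersion), with library batch as a term in melan-a. P-values were adjusted by the Benjamini-Hochberg method over the tested sites. A site was called at an adjusted p under 0.05 with a difference of at least 10 percentage points between group means of the plain ratio; in melan-a the difference is the mean of the differences within the 2 batches. Mean methylation per library was compared by two-sided exact permutation, over 10 splits in HEMn-DP1 (smallest p 0.1) and over 100 arrangements within batches in melan-a (smallest p 0.01). Sites were classed as low (under 20%), middle or high (over 80%) by their mean over all libraries of the cell type. The agreement of the 2 melan-a batches was measured by the correlation of their differences across sites. These tests, their alternatives and the rule for named sites were set before the data were examined.

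The rule for named sites took, per cell type, the 10 largest gains and the 10 largest losses among called sites whose groups did not overlap, or, in melan-a, whose difference had the same sign in both batches. With fewer than 10 called in a direction, 5 sites were taken by the smallest unadjusted p among those with a difference of at least 10 percentage points. The rule also asked for sites near genes of fixed lists. An annotation of hg19 or mm9 was not used here, so genes, gene lists, genes shared between the cell types and marker genes of other skin cell types are not analysed here, and sites are named by the position the files give.

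The fit was tested on simulated reads drawn from the real levels and depths, with 200 sites of middle methylation changed at each size. The sizes are nominal. Changed levels were kept inside the scale, so sites with little room in the chosen direction changed by less, most of all at the largest size. The spread was the variance of observed log odds within groups (and batches), shuffled over all tested sites. Counting error, already part of that variance, was added again. The simulated spread is thus not that of the changed sites, and the counts recovered do not give the power of the real comparisons. In the simulated HEMn-DP1 comparison over 70144 sites, 0 of 200 sites were recovered at nominal changes of 10, 20 and 40 percentage points. In the simulated melan-a comparison over 19398 sites, 1, 22 and 154 of 200 were recovered at these sizes. There were 0 false calls in either.

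Alternatives were a coverage minimum of 10, 50 or 100 reads, other size and p thresholds, a likelihood ratio test, limma 3.58.1 on log2((methylated + 0.5)/(unmethylated + 0.5)) and on the authors' adjusted percent, a shift of each library by its median over low sites, the replicate number as a block, no batch term, each batch alone, the sex chromosomes of the mouse line included, and each library left out. Added after the data were seen were a shift by the median over middle sites, the authors' factor as an offset, a quasi-binomial spread, the sum of HEMn-DP1 UVR 1 and 2 and of melan-a UVR 1, 2 and 3, and classes of sites by distance to the nearest CCCGGG site the files list. Replicate numbers are those of the sample titles; the deposited files carry other numbers for some libraries of both cell types. Correlations between same-numbered control and UVR libraries of their deviations from the mean of the group and batch were -0.0963 to -0.0531 in HEMn-DP1 and, for the 4 pairs within a batch, -0.0356 to 0.140 in melan-a. They were not all over 0.1, so replicate numbers were not used as pairs. The sex chromosomes and copy number of the human cells were not analysed.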

Results

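Melanocytes of 2 kinds were irradiated and grown on for 1 month before DNA methylation was measured at CCCGGG sites: HEMn-DP1, cultured human epidermal melanocytes, and melan-a, an immortal line of mouse melanocytes. Irradiated dishes (UVR) received 175 J/m2 of broadband ultraviolet light, 35% UVA and 65% UVB, in 90 s at 1.94 W/m2. There were 3 control and 3 UVR libraries of HEMn-DP1, and 5 control and 5 UVR libraries of melan-a in 2 batches, batch 1 with 2 control and 3 UVR libraries and batch 2 with 3 control and 2 UVR libraries. Total reads, where M stands for 1000000 reads, were 161, 20.95 and 29.6 M in the HEMn-DP1 control libraries 1 to 3 and 92.2, 42.8 and 19.9 M in UVR 1 to 3. In melan-a they were 6.48, 2.90, 8.08, 2.98 and 14.6 M in control 1 to 5 and 10.3, 4.95, 7.41, 4.53 and 14.9 M in UVR 1 to 5. The labels call the dishes biological replicates and do not say whether they stayed separate over the month, so p-values measure the spread between these libraries.

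Tested sites were classed by their mean methylation over all libraries of a cell type. Of 70144 tested HEMn-DP1 sites, 39.3% had a mean under 20%, 38.8% a mean over 80%, and 21.8% lay between. In melan-a 55.5% of 19398 tested sites were low, 22.7% high and 21.8% in the middle. HEMn-DP1 sites with another CCCGGG site listed in the files within 100 bp averaged 28.5% ± 0.514 (SD, n = 3) in control libraries, against 44.7% ± 1.16 with the nearest one over 100 and up to 500 bp away, 68.8% ± 0.973 over 500 and up to 2000 bp and 91.1% ± 2.57 at over 2000 bp. In melan-a the means were 15.0% ± 1.66 (SD, n = 5) within 100 bp and 36.9% ± 2.72 over 100 and up to 500 bp; sites over 500 and up to 2000 bp away, 404 in number, averaged 20.6% ± 4.26. These distance classes were chosen after the data were seen.

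The first comparison asked whether UVR left a lasting change of methylation in HEMn-DP1 cells. Mean methylation over all tested sites was 49.8% ± 0.829 (SD, n = 3) in control and 48.8% ± 0.620 (SD, n = 3) in UVR libraries, a difference of -1.02 percentage points (two-sided exact permutation p = 0.2; 0.1 is the smallest p of this design). Middle sites averaged 57.9% ± 2.51 in control and 53.8% ± 2.63 in UVR libraries (exact permutation p = 0.2). Low sites averaged 1.98% ± 0.315 and 1.28% ± 0.243 (exact permutation p = 0.1), with every UVR library below every control library. High sites averaged 93.7% ± 1.05 and 94.1% ± 0.433 (exact permutation p = 0.8). Over the 8 classes of all, low, middle and high sites and of neighbour distance, the adjusted p was at least 0.32.

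No HEMn-DP1 site was called: 0 of 70144 sites passed edgeR's quasi-likelihood test, 5226 had an unadjusted p under 0.05, and limma called 0 on log ratios and 0 on the authors' adjusted percent. The likelihood ratio test of edgeR called 88 sites, 13 higher and 75 lower in UVR libraries. Sites with lower means in UVR libraries were more numerous, 8381 lower and 5629 higher by at least 10 percentage points, but 3 of the other 9 splits of the same libraries were more uneven, up to 6251 against 3112. The groups did not overlap at 3443 higher and 4648 lower sites, together 11.5% of sites. Chance gives at most 10%, and less where libraries tie at the same level. The other 9 splits gave 4.51% to 15.0%. The simulated comparison recovered no site even at a nominal change of 40 percentage points, which was smaller at sites with little room. Its spread was also not that of the sites changed. It cannot tell which changes the real comparison could have found, so a count of 0 does not show that changes of that size were absent.

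The 10 named HEMn-DP1 sites, 5 per direction with the smallest unadjusted p among differences of at least 10 percentage points, did not pass the test (adjusted p 0.307 to 0.525, edgeR) and are given as values, with hg19 positions. With a minimum of 10 reads the first 4 of the lower ones passed it (adjusted p = 0.0403, edgeR). The lower ones lay near full methylation in control libraries. At position 3880230 of chromosome 17 the level was 97.6% ± 2.56 (SD, n = 3) in control and 34.8% ± 8.60 (n = 3) in UVR libraries, over 78 to 726 reads per library. At position 4653579 of chromosome 7 it was 98.9% ± 0.566 and 62.8% ± 8.69, and at position 133894440 of the same chromosome 99.1% ± 0.970 and 68.8% ± 9.16. Position 41064501 of chromosome 15 had 99.2% ± 0.115 and 67.1% ± 3.26, and position 47537805 of chromosome 21 had 99.2% ± 0.765 and 71.8% ± 4.68. Of the higher ones, 4 lay near 0 in control libraries. Position 42712836 of chromosome 6 had 2.79% ± 2.74 in control and 43.2% ± 10.8 in UVR libraries, position 31655921 of chromosome 19 had 1.89% ± 0.938 and 30.2% ± 10.4, and position 79917231 of chromosome 17 had 1.22% ± 0.652 and 20.2% ± 2.24. Position 45867903 of chromosome 17 had 0.00674% ± 0.0117 and 15.3% ± 13.8. There UVR 1, 2 and 3 stood at 26.7%, 19.1% and 0%, so the groups overlapped and the rise came from UVR 1 and UVR 2. The fifth, position 44559837 of chromosome 22, had 79.1% ± 20.4 in control and 99.7% ± 0.105 in UVR libraries.

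HEMn-DP1 libraries differed widely within groups. Over middle sites, with 1 shift of log odds per pair removed, the spread between 2 libraries beyond counting error was 16.0 to 27.1 percentage points between control libraries. It was 17.8 to 34.2 between a control and a UVR library. UVR 1 and UVR 2 differed by 4.61 percentage points, 2.84 times the variance that counting allows, while UVR 3 differed from them by 25.8 and 23.8. With the reads of UVR 1 and UVR 2 summed as 1 library, an alternative chosen after the data were seen, 0 sites were called.

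**Figure D1:**
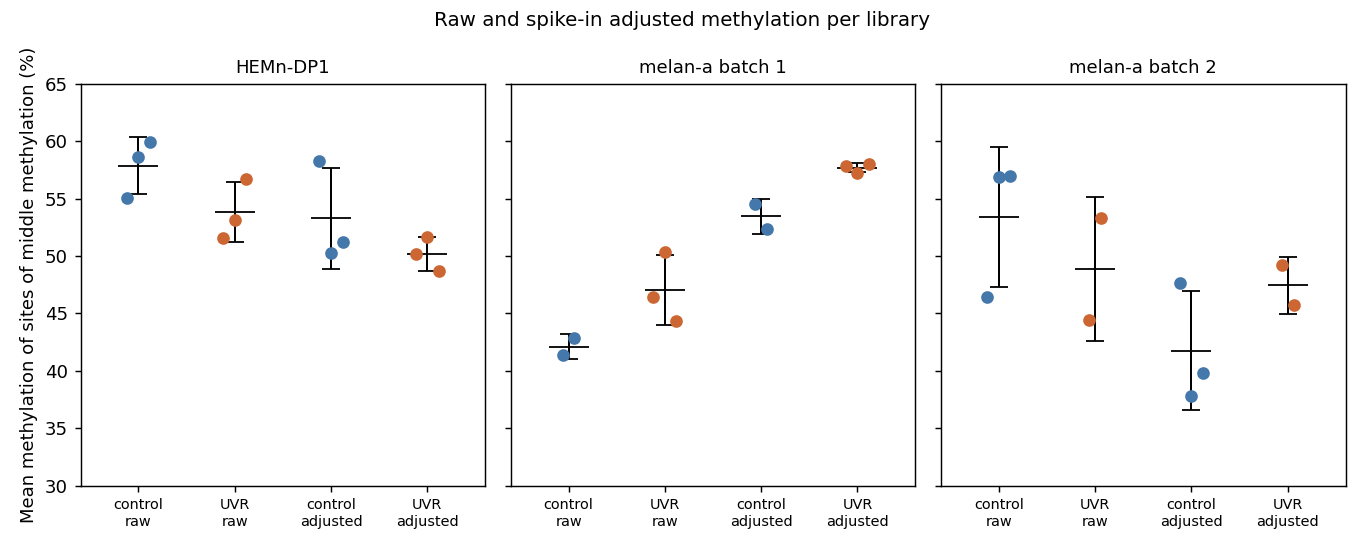
Mean methylation (%) of sites of middle methylation, raw and after the authors' adjustment by spiked standards, for HEMn-DP1 and for each melan-a batch; each point is a library (blue control, orange UVR) and bars give the mean and SD. In melan-a batch 2 the raw control mean, 53.4%, lies above the UVR mean, 48.9%, and the adjusted control mean, 41.8%, below the UVR mean, 47.5%.

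The second comparison asked the same of melan-a cells. Mean methylation over tested sites was 33.6% ± 2.61 (SD, n = 5) in control and 33.5% ± 1.27 (SD, n = 5) in UVR libraries, and the mean of the within-batch differences was 0.373 percentage points (two-sided exact permutation within batches, p = 0.73). In batch 1 the control mean was 31.2% (n = 2) and the UVR mean 33.4% (n = 3), a difference of 2.18 percentage points. In batch 2 these were 35.1% (n = 3) and 33.7% (n = 2), a difference of -1.43. At middle sites the differences were 4.92 percentage points in batch 1 and -4.54 in batch 2. With the authors' adjusted percent the difference over all sites was 1.80 percentage points in batch 1 and 1.97 in batch 2 (exact permutation p = 0.05, adjusted p = 0.05 over 8 site classes), so the sign in batch 2 depended on the adjustment.

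At single sites melan-a UVR libraries differed from controls at 1529 of 19398 sites (edgeR, adjusted p under 0.05), of which 813 gained and 716 lost methylation. Gained sites had a median of 29.7% in batch 1 controls and 88.1% in batch 1 UVR libraries, and lost sites 79.0% and 20.4%. In batch 2 the medians were 61.4% in control and 64.7% in UVR libraries at gained sites, and 65.4% and 47.4% at lost sites. The mean difference at gained sites was 44.0 percentage points in batch 1 and 2.54 in batch 2, where 593 of 813 sites were higher. At lost sites it was -40.7 in batch 1 and -11.9 in batch 2, where 708 of 716 were lower. These batch 2 values depended on the scale: with the authors' adjusted percent the mean was 10.8 at gained sites, 801 of 813 higher, and -3.27 at lost sites, 555 of 716 lower, and with each library shifted by its median over middle sites it was 6.19 and -8.08. The UVR minus control difference itself differed between batches at 2746 sites (edgeR interaction term, adjusted p under 0.05 and differences at least 10 percentage points apart). It was larger in size in batch 1 at 2737 of them. This fit took UVR 1, 2 and 3 as separate libraries and was not repeated with them summed.

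Batch 1 alone gave 6453 called sites of 24463 tested, 4499 gained and 1954 lost, and batch 2 alone gave 0 of 21194, with 552 at an unadjusted p under 0.05; limma on log ratios of both batches called 0, with 4101 at an unadjusted p under 0.05. With the reads of UVR 1, 2 and 3, which differed little beyond counting error, summed as 1 library, an alternative chosen after the data were seen, the count over both batches was 42, 5 gained and 37 lost. Without control 1 the count was 205, without control 2 it was 295, without UVR 1, 2 or 3 it was 635, 878 or 693, and the split turned to 1690 gained and 625 lost with the authors' factor as an offset and to 1240 gained and 70 lost with limma on their adjusted percent.

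**Figure D2:**
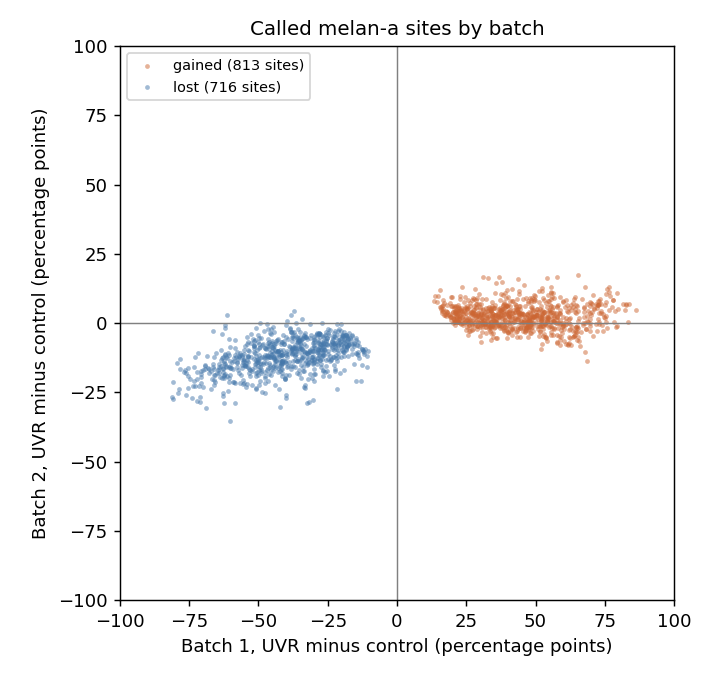
UVR minus control difference of mean methylation (percentage points) in batch 1 (x axis) and in batch 2 (y axis) at the 1529 called melan-a sites; each point is a site, orange gained and blue lost. Gained sites average 44.0 in batch 1 and 2.54 in batch 2, and lost sites -40.7 and -11.9, on the scale of the plain ratio of counts.

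The named losses, the 10 largest with the same sign in both batches, fell by means of 49.7 to 54.1 percentage points (adjusted p 6.65e-08 to 3.62e-06, edgeR; 21 to 1660 reads per library; mm9 positions). At position 95045395 of chromosome 11 the level was 90.3% ± 12.2 (SD, n = 2) in control and 9.38% ± 3.17 (n = 3) in UVR libraries of batch 1, and 66.4% ± 4.09 (n = 3) and 39.2% ± 6.89 (n = 2) in batch 2. Position 34896932 of chromosome 14 went from 84.8% ± 18.6 to 3.62% ± 0.818 in batch 1, with 63.8% ± 8.70 in batch 2 controls. Position 91773401 of chromosome 1 went from 89.7% ± 8.37 to 10.7% ± 2.89 in batch 1, and position 105335416 of chromosome 7 from 84.2% ± 18.4 to 5.55% ± 1.38. The others were positions 139424198 and 150526991 of chromosome 7, 50482357 of chromosome 11, 45602932 of chromosome 13, 43487428 of chromosome 9 and 120945520 of chromosome 1. Over the 10, batch 2 differences were -21.1 to -30.6 percentage points.

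The named gains, likewise 10, rose by means of 43.4 to 45.5 percentage points (adjusted p 2.90e-06 to 6.00e-05, edgeR; 40 to 786 reads per library). Position 127810526 of chromosome 8 went from 9.27% ± 5.19 (SD, n = 2) to 95.4% ± 3.40 (n = 3) in batch 1, and was 59.9% ± 5.07 (n = 3) in control and 64.8% ± 6.42 (n = 2) in UVR libraries of batch 2. Position 127810208, on the same chromosome, went from 8.70% ± 4.34 to 91.4% ± 0.124 in batch 1. Position 6810640 of chromosome 6 went from 7.65% ± 4.06 to 91.4% ± 0.832 and position 97578042 of chromosome 16 from 5.53% ± 5.87 to 84.9% ± 5.58. The others were positions 121076626 and 121177978 of chromosome 8, 120118173 and 4167386 of chromosome 11, 117095783 of chromosome 13 and 39550590 of chromosome 18. Over the 10, batch 2 differences were 4.59 to 13.03 percentage points. With UVR 1, 2 and 3 summed, all 10 losses passed the test and 1 of the 10 gains, position 4167386 of chromosome 11 (adjusted p = 0.0413, edgeR). None of the 20 named sites was called in batch 2 alone or by limma on log ratios; 3 were called in batch 2 alone with the shift by middle sites.

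Called melan-a sites were fewer where another listed site lay within 100 bp, at 1.84% of 2666 such sites for gains and for losses, against 4.57% and 3.99% elsewhere (Fisher's exact test, adjusted p 4.27e-11 and 4.23e-08 over 46 tests). Sites that close averaged 15.0% in controls, and a low level leaves less room for a loss of 10 percentage points. Over 100 and up to 500 bp 4.58% of 16319 sites gained and 4.06% lost methylation, against 2.14% and 1.72% elsewhere (Fisher's exact test, adjusted p 5.58e-10 and 1.89e-10). Most sites elsewhere are the 2666 within 100 bp, so this is nearly the same contrast and not a second result. Over 500 and up to 2000 bp losses were again fewer, 4 of 404 sites against 3.75% of the others (Fisher's exact test, adjusted p = 0.00954). Low sites made up 79.1% of those within 100 bp, 51.4% over 100 and up to 500 bp and 65.8% over 500 and up to 2000 bp. The tests by distance, for gains and for losses, do not separate distance from level. Chromosome 1 held more losses than the rest, 5.96% of its 1074 sites against 3.56% (adjusted p = 0.00148), and chromosome 13 more gains, 6.37% of 628 sites against 4.12% (adjusted p = 0.0422). Losses were fewer on chromosome 3, 1.73% of 809 sites (adjusted p = 0.0101), and on chromosome 5, 2.40% of 1499 (adjusted p = 0.0247). Sites within 1000 bp can share a DNA fragment, and their differences went together (correlation of differences between neighbours over 100 and up to 1000 bp apart 0.452 across site pairs), so these p-values, which take sites as independent, are too small.

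Chaining tested sites within 1000 bp, a grouping chosen after the data were seen, gave 21 regions with at least 3 called sites of 1 direction and none of the other, 9 gained and 12 lost; 0 regions with 3 or more called sites mixed directions. By the mean of the 2 batch differences, the largest loss was at 35090256 to 35091799 of chromosome 11, from 74.3% ± 11.1 (n = 2) to 15.5% ± 3.01 (n = 3) in batch 1 and from 64.5% ± 7.09 (n = 3) to 45.8% ± 5.47 (n = 2) in batch 2, followed by one at 35055768 to 35056490 of the same chromosome, from 62.3% ± 18.6 to 9.02% ± 2.95 in batch 1 and from 56.8% ± 10.6 to 35.4% ± 9.15 in batch 2. At 120944614 to 120945520 of chromosome 1 all 5 tested sites lost methylation. The largest gain by that mean, at 6810640 to 6811036 of chromosome 6, went from 8.79% ± 6.17 to 79.1% ± 1.21 in batch 1, with 45.8% ± 10.96 and 49.7% ± 11.5 in batch 2. At 120623208 to 120623873 of chromosome 8 the mean went from 21.2% ± 0.146 to 85.3% ± 3.35 in batch 1 and was 51.0% ± 13.5 and 49.8% ± 10.8 in batch 2.

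The differences of the 2 melan-a batches correlated across the 19398 sites with Pearson's r = 0.455 and Spearman's rho = 0.255, and had the same sign at 47.0% of sites; sites are not independent replicates. The sign was shared at 60.6% of sites with the shift by middle sites and at 58.1% with the authors' adjusted percent. At sites called in batch 1 alone that were tested in both, 4556 in number, r was 0.647 and the sign was shared at 64.6%. These sites were chosen by their batch 1 difference, which by itself can raise r, so 0.647 does not show closer agreement than 0.455. Of 1652 lost sites 1530 were lower in batch 2, and of 2904 gained sites 1414, or 48.7%, were higher, where 33.8% of all 19398 tested sites were higher. Which direction was shared more often depended on the scale: with the authors' adjusted percent 801 of the lost sites were lower and 2694 of the gained sites higher, and with the shift by middle sites 1309 and 2230; of all tested sites 62.8% and 51.7% were higher on these scales. A correlation as high came from 5 of the 100 splits within batches, the real one included, and from 4 on either of the other scales.

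In melan-a the libraries grouped by batch and treatment once 1 shift of log odds per pair was removed. Without that shift removed, control 3 and UVR 5 of batch 2 lay nearer to the other group of their batch by mean absolute difference over middle sites. Over middle sites the spread between libraries beyond counting error was 28.3 to 31.9 percentage points between control and UVR in batch 1 and 5.03 to 7.88 in batch 2. Controls of batch 1 differed from those of batch 2 by 12.7 to 18.2 and UVR libraries of the 2 batches by 15.3 to 16.2. Within a group and batch it was 1.46 to 5.39, lowest among UVR 1, 2 and 3, whose pairs had 1.15 to 1.31 times the variance that counting allows and were kept as separate libraries, as the labels give them. Read depth of chromosome 6 moved with the same groups. Depth was taken relative to each site's mean over all melan-a libraries, and then to the median autosome of each library. A value of 1 is thus near the average of these libraries and does not stand for a number of copies. For chromosome 6 it was 0.864 ± 0.0307 (SD, n = 2) in control and 1.19 ± 0.0286 (n = 3) in UVR libraries of batch 1. In batch 2 it was 0.941 ± 0.0223 (n = 3) and 1.01 ± 0.00699 (n = 2). The exact permutation within batches gave p = 0.01, the smallest it can give, and an adjusted p = 0.0667 over 20 chromosomes. Chromosome X went the other way, 1.04 ± 0.0369 and 0.898 ± 0.0218 in batch 1 and 1.08 ± 0.0299 and 1.03 ± 0.0283 in batch 2, with the same p, and so did chromosome 15, 1.05 ± 0.000834 and 0.961 ± 0.00932 in batch 1 and 1.01 ± 0.0111 and 0.980 ± 0.0143 in batch 2.

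**Figure D3:**
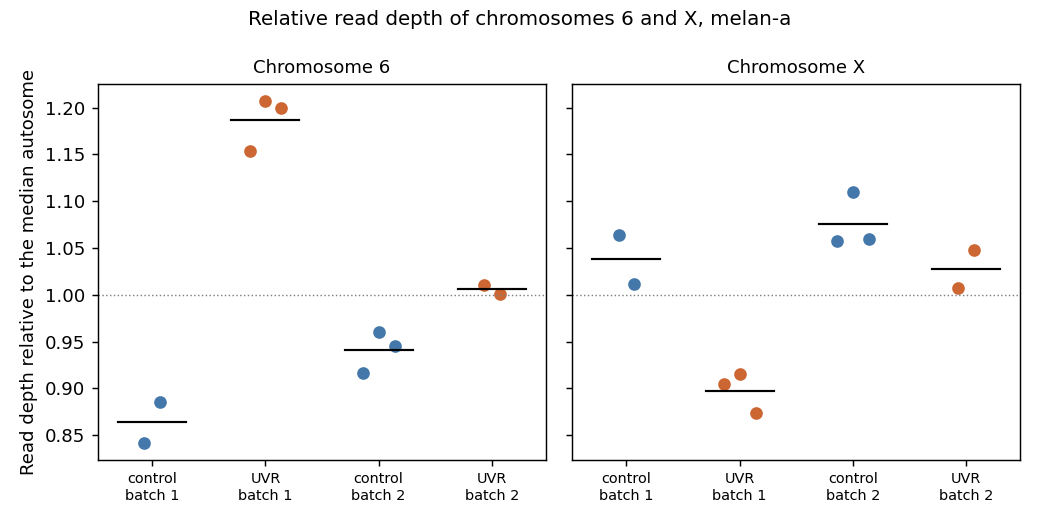
Read depth of chromosomes 6 and X per melan-a library (blue control, orange UVR), by batch. Depth is relative to each site's mean over all melan-a libraries and then to the median autosome of the library. Lines are group means and the dotted line is 1, near the average of these libraries. For chromosome 6 the means are 0.864 and 1.19 in batch 1 and 0.941 and 1.01 in batch 2.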

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

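The counts over other splits were planned for the called sites and for the correlation of plain ratios. The other tests in this part, with the split counts of the correlation on the other scales, were chosen after the values they concern had been seen. The UVR minus control difference of methylation was not the same in the 2 melan-a batches at 2746 sites, by the batch by UVR term of the fit. That term does not show that UVR was the cause. Relative read depth of chromosome 6, which no comparison of methylation uses, was higher in melan-a UVR than control libraries of batch 1. The group means differed by 0.323, on the scale where 1 is near the average of the melan-a libraries, and every UVR library lay above both control libraries. The largest difference of any other autosome in either direction was 0.0899, a lower depth on chromosome 15.

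The large differences of melan-a batch 1 and the small ones of batch 2 were weighed first. A difference in enzyme digestion between libraries would shift the log odds of all sites of a library by a like amount, but with each library shifted by its median over middle sites 6201 sites were still called in batch 1. By the spread beyond counting error, with 1 shift of log odds per pair removed, 0 of 10 libraries lay nearer to the other group of their batch. By the mean absolute difference without that shift, 2 libraries of batch 2 did. Control 3 differed by 7.23 and 8.48 percentage points from UVR 4 and 5, and by 10.9 and 10.8 from controls 4 and 5. UVR 5 differed by 9.46 from UVR 4 and by 6.39 to 8.48 from controls. These values argue against single libraries swapped in batch 1 and leave batch 2 undecided. Groups labelled the wrong way round as a whole would give the same count, so that case was not tested. Copies of chromosome 6 acting on their own sites leave most of it unaccounted for, since 5.36% of called sites lie there, and a mixture of 2 cell populations with different numbers of chromosome 6 would make batch 2 differences a fixed share of those of batch 1, equal to the share of the depth differences. The slope of batch 2 on batch 1 differences was 0.135 and the ratio of depth differences 0.201. The slope was taken on levels shifted by middle sites, at 4521 sites chosen by their batch 1 difference. Slope and ratio differed by -0.0663, more than the 1 jackknife standard error (0.0346) set as the limit for a match. The 95% jackknife interval over the 10 libraries, -0.151 to 0.0183, includes 0, so the mixture is not borne out but stays open. UVR exposure itself stays open too, since 64.6% of the sites called in batch 1 alone had the same sign in batch 2, or 77.7% with the shift by middle sites, a share that cultures drifting apart over the month could also give.

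Among all HEMn-DP1 pairs of libraries, UVR 1 and UVR 2 were the closest, with a spread of 4.61 percentage points beyond counting error against 16.0 to 34.2 for the other 14 pairs. 1 library deposited as 2 would differ by counting alone, and the variance between the 2 was 2.84 times that. Whether the 2 libraries were made from 1 culture or DNA cannot be told apart from 2 cultures that stayed alike, because the labels do not trace the dishes; no biological explanation was tested.

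The authors' adjustment turned the batch 2 difference of melan-a middle sites from -4.54 to 5.70 percentage points. A factor that offsets a real shift of a library would go with log odds of its middle sites that move by -1 per unit of log factor among libraries of the same group and batch, whereas the slope was -0.597 (-0.717 to -0.572 with each library left out), and -0.455 in HEMn-DP1. This is consistent with factors that are larger than the shift of the genomic sites; whether the standards or the genomic sites give the better estimate of digestion was not tested, and no biological explanation was tested.

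For the count of called melan-a sites, 2 of 100 splits within batches gave as many, the real one with 1549 sites (with the dispersion taken from 3000 sites) and 1 other with 1683. This share is under the limit of 0.05 set beforehand. That other split kept the labels of batch 1 and exchanged 1 control and 1 UVR library of batch 2, and all 6 splits with any call kept the labels of batch 1. The count thus rests on a structure of the samples in batch 1. Chance is not excluded by the share, since the 10 splits of batch 1 are too few for a share under 0.05. In that batch UVR 1, 2 and 3 had 1.15 to 1.31 times the variance that counting allows, the labels do not say whether their cultures stayed separate over the month, and with their reads summed as 1 library 42 sites were called. For the correlation between batches, 5 of 100 splits gave a value as high as 0.455, the highest of the others 0.573, so chance is not excluded. That split set controls 1 and 2 and UVR 2 against UVR 1 and 3 in batch 1, and controls 3 and 5 against control 4, UVR 4 and UVR 5 in batch 2. It kept much of the real grouping with sides exchanged in both batches, so it is not free of the real structure. With the labels of batch 1 kept, only the real split of 10 in batch 2 gave a value as high, the highest other 0.314. Those 10 splits are too few for a share under 0.05. With the shift by middle sites (0.576, highest other 0.594) or the authors' adjusted percent (0.528, highest other 0.588) 4 of 100 splits gave a value as high as the real one. This share is just under 0.05, so the outcome depends on the scale. For HEMn-DP1, the 10 splits are too few for a share under 0.05; the real split gave 0 sites and the highest other 0, so that all 10 gave as many.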

How the results depend on the processing

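The shifts by middle sites and by the authors' factor, the quasi-binomial spread, the single batches with a shift, the mean difference within single batches, the summed libraries, and the authors' adjusted percent for the correlation were chosen after seeing the data; the rest were planned. The HEMn-DP1 count of 0 called sites became 4 with at least 10 reads, 88 with the likelihood ratio test, 307 with a quasi-binomial spread and 0 to 1 with each library left out, and stayed 0 under the other alternatives apart from the block given last. The melan-a count of 1529 became 324 with at least 100 reads and 997 with at least 20 percentage points, both by construction a narrower set. It became 617 with the shift by low sites, 705 with no batch term, 235 with a quasi-binomial spread and 2315 with the authors' factor; the cause was not tested. It was 0 with limma on log ratios; the cause was not tested. With UVR 1, 2 and 3 summed as 1 library it was 42, and 5426 in batch 1 alone, with fewer libraries and, in batch 1 alone, the lone UVR library assumed to vary like the controls. Batch 1 alone gave 6453, or 6201 with the shift by middle sites and 6751 with the authors' factor, and batch 2 alone 0, 23 and 0, with fewer libraries in each. Leaving out 1 library gave 205 to 1726. With the replicate number as a block, 13 HEMn-DP1 and 0 melan-a sites were called; the numbers are those of the titles, from which numbers in the deposited files differ for some libraries, and were not taken as pairs; no HEMn-DP1 pair had a correlation over 0.1, and melan-a number 3 joins 2 batches.

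The HEMn-DP1 difference of mean methylation, -1.02 percentage points, was -1.02 with the block too and -3.29 with pooled reads, ran from -1.46 to -0.644 with each library left out, and turned to 0.365 in high sites; the cause was not tested. That of melan-a, 0.373, turned to -1.96 with pooled reads and -0.0510 with batches ignored. It ran from -0.360 (without UVR 5) to 1.11 with each library left out, with -0.232 without control 3. The cause was not tested, and none of these passed the test. It was 3.49 in batch 1 alone (exact permutation p = 0.1) and -1.47 in batch 2 alone (exact permutation p = 0.5). A single batch has 10 splits and a smallest p of 0.1, so it could not pass the test. These 2 differences were taken over the 24463 and 21194 sites with at least 20 reads in every library of the batch. The differences of 2.18 and -1.43 in Results were taken over the 19398 sites tested in both. The correlation between batches, 0.455, was 0.617 at middle sites and 0.576 with the shift by middle sites, and 0.279 (without UVR 5) to 0.597 (without UVR 4) with each library left out; the cause was not tested. The 20 named melan-a sites kept their call in 466 of 596 refits in which they were tested, and the 10 named HEMn-DP1 sites passed the test in 27 of 177; a kept direction shows nothing here, since the sites were chosen by it. Gene lists, genes shared between the cell types and their alternatives were not run, since no annotation of the builds was used here. Depth limits the shallowest libraries, with a median of 97 reads per site in melan-a and 178 in HEMn-DP1.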

Other observations

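The tests in this part were chosen after the values had been seen. At the 4521 melan-a sites called in batch 1 alone after the shift by middle sites and tested in both batches, batch 2 controls lay between batch 1 control and batch 1 UVR levels at 84.6% of sites. These sites were chosen by their batch 1 difference, which by itself favours places between the batch 1 groups for other libraries. On a scale with 0 at the mean of batch 1 controls and 1 at the mean of batch 1 UVR libraries, controls 3, 4 and 5 stood at 0.405, 0.458 and 0.406 and UVR 4 and 5 at 0.557 and 0.558. The relative depth of chromosome 6 in these 5 libraries was 0.917, 0.961, 0.945, 1.01 and 1.00. In 20000000 bp windows along chromosome 6 the ratio of UVR to control depth in batch 1 was 1.31 to 1.499 in the 7 windows after the first and 1.12 in the first, and in batch 2 it was 1.04 to 1.13 and 0.999.

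A hypothesis for follow-up is that the 2 melan-a batches may have started from cultures of different makeup, since unirradiated controls differed between batches by 12.7 to 18.2 percentage points over middle sites. The test at hand, the slope of 0.135 against a depth ratio of 0.201, differed by -0.0663 with an interval that includes 0 (-0.151 to 0.0183), so it decides neither for nor against 2 populations marked by chromosome 6, and no test here separates growth of pre-existing cells from change within cells.

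HEMn-DP1 differences between neighbouring sites correlated less than those of melan-a, with r = 0.0839 across 30923 pairs of adjacent sites over 100 and up to 1000 bp apart against 0.452 across 10628 pairs in melan-a. Over 1000 and up to 10000 bp the correlations were 0.00878 and 0.198.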
